A study of Homo sapiens with 12 samples.

How the data were processed

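The deposited table held raw counts of reads per gene symbol from total RNA (Nextera libraries), which, per the labels, the authors made by aligning to hg19 with STAR. They also named DESeq2, with no role, and the versions, the counter, the annotation, the strand setting and the model are not given in the sources used here. The table had 12 columns, all used, and 2709 of its 20114 symbols had no count. Other products of the study were not analysed here. From the counts on, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Genes were kept by filterByExpr with the 6 groups (13872 genes), libraries were scaled by TMM, and edgeR's quasi-likelihood F test (robust) was run on 1 fit with a coefficient for each group and 6 residual degrees of freedom. A call was an adjusted p under 0.05 (Benjamini-Hochberg over the genes tested in a comparison), with no fold threshold. Limma's camera, with a preset correlation of 0.01 between genes, tested 35 of the 37 lists in each comparison, adjusted over the lists, and the lists of immune (4 tested members) and endothelial markers (2) were too short for it. Comparisons, tests, lists and the rule for naming genes were fixed before the data were examined.

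Genes were named by a rule: against vehicle, the 8 largest called rises and 8 largest called falls with an average log2 CPM of at least 2 and both treated libraries on the same side of both vehicle libraries. For 10 nM against 100 pM, the differences between times and vehicle over time these were 5 and 5, without the condition on libraries for the differences between times. Of the opposed genes, the 5 whose smaller step was largest were named. From each list up to 4 called members with the smallest adjusted p were eligible, and for length the text gives 2, or none, where more than 5 were called. PGR, ESR1, NR3C1, FKBP5, CCND1, MYC, MKI67 and GREB1 were always reported, some genes that the rule names are not reported here, and clone names, antisense genes and pseudogenes were counted but not named. A fold against a group with no count used a floor of 3 counts per library, and a ratio against a group with 1 to 3 counts has an exact 95% binomial counting interval. Reads copied by PCR carry no molecular identifiers, so floors and counting intervals cover counting error only.

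Libraries with the same replicate number moved together: deviations from the group mean correlated between groups with r of 0.464 to 0.677 (median 0.558, across genes, over 15 pairs of groups). Nothing in the labels says what the numbers share, so the block on replicate number was kept as an alternative (5 residual degrees of freedom), where the biological coefficient of variation went from 0.163 to 0.0678. Within a group the replicates differed by 44.2 to 66.6 chi-square per degree of freedom, above the 1 of repeated sequencing of 1 library. Groups of 2 allow no test of a single library standing apart and no other split of the samples. When a library was left out, the lone library of its group was assumed to vary like the other groups. A self-test changed 200 of 13872 genes in simulated counts (10 nM against vehicle at 6 h). Of 1.5-fold, 2-fold and 4-fold changes edgeR called 11.9%, 55.2% and 87.9% (6 false calls) and DESeq2 37.3%, 77.6% and 97.0% (37). With the block edgeR called 13.4%, 52.2% and 87.9% (5). In the data the block raised 5826 calls to 8662, so self-test rates need not hold there. Of 200 genes simulated as opposed by 2-fold, 67% were called with 3 false calls, unchanged comparisons gave 0 calls, and a dose ratio set to 0.5 was measured as 48.9%.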

Results

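T47D, a human breast carcinoma line that carries progesterone and estrogen receptors, was serum-starved and then given vehicle or a progestin, a ligand of the progesterone receptor, at 100 pM or 10 nM. RNA was taken at 6 h and 18 h, with 2 libraries in each of the 6 groups, numbered replicate 1 and replicate 3. The series title raises the question of whether cells give different outputs at different progestin levels, which the comparisons of each dose with vehicle and of the doses with each other address. Total counts ran from 34204970 to 41373890 per library, and 13872 of the 20114 genes in the table had enough counts to test. Values in parentheses after a gene are log2 fold changes ± SE, and levels are counts scaled to library size (CPM) as mean ± SD (SD, n = 2). Where a call changed, or a count moved by more than 1.5 times, when replicate number was added to the fit as a block, that value is given as with the block, single libraries are written as dose and replicate number, such as vehicle 1, and with that time alone stands for a fit to the 6 libraries of 1 time. All p-values measure only the spread between these samples, since nothing says that the libraries of a group came from separate cultures.

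The libraries separated by dose more than by time. Component 1 of the 2000 most variable genes held 58.5% of the variance and ran from the vehicle to the 10 nM libraries. On component 2 (15.9%) the 100 pM libraries lay above vehicle and 10 nM of the same time, overlapping 10 nM only across times. Component 3 (9.14%) followed the replicate number. The share of counts from the 13 mitochondrially encoded genes was 6.69% to 10.8% and was higher in replicate 3 than in replicate 1 in each of the 6 groups.

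**Figure D1:**
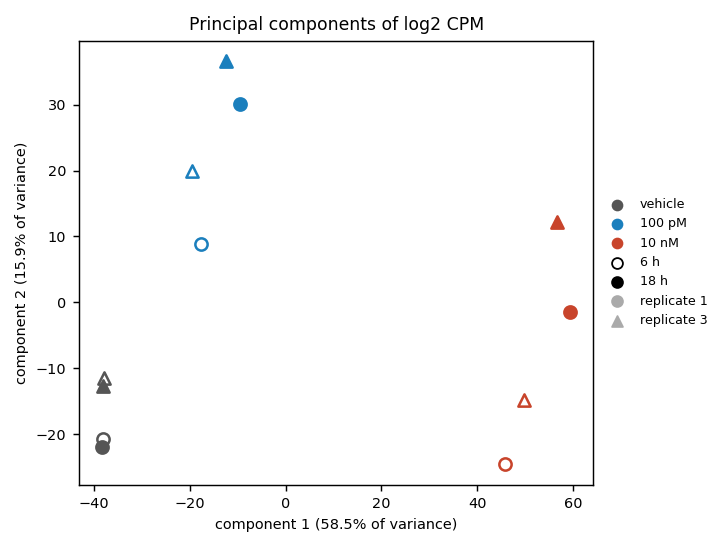
Positions of the 12 libraries on the first pair of principal components of log2 CPM, coloured by dose, with open symbols for 6 h, filled symbols for 18 h, circles for replicate 1 and triangles for replicate 3.

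At 100 pM for 6 h the largest rises were in SGK1 (8.11 ± 0.60), a kinase induced by glucocorticoids and progestins, APLN (7.26 ± 0.32), the peptide ligand of the apelin receptor, and TRIM22 (5.27 ± 0.48), an antiviral ubiquitin ligase. SGK1 went from 0.179 ± 0.109 CPM in vehicle to 50.2 ± 17.1 CPM (SD, n = 2), and APLN from 0.166 ± 0.0550 to 25.9 ± 3.31 CPM. Next came ZBTB7C (4.76 ± 0.52), a zinc finger transcription factor, SLC25A18 (4.71 ± 0.40), a mitochondrial glutamate carrier, ANKRD35 (4.68 ± 0.60) and ZBED2 (4.51 ± 0.79). SCRG1, a secreted protein, had no count in vehicle and was at least 2.21-fold higher at 100 pM (floor of 3 counts per library). The largest falls were in AMIGO2 (-2.43 ± 0.19), a neuronal adhesion protein, KCNK5 (-1.89 ± 0.30), a potassium channel, MKX (-1.86 ± 0.22), a homeobox factor, and BCL2 (-1.71 ± 0.33), which blocks apoptosis. DCDC2 (-1.50 ± 0.23) and PCED1B (-1.44 ± 0.25) fell too, as did CXCL12 (-1.32 ± 0.21), a chemokine, and DOCK10 (-1.20 ± 0.18), an exchange factor. The 16 genes had edgeR adjusted p values of 2.13e-05 to 0.0264. edgeR called 399 genes up and 84 down, 230 and 18 of them by more than 2-fold. The total of 483 became 1696 with the block, 836 with DESeq2, 221 without vehicle 1, 260 without vehicle 3, 308 without 100 pM 1 and 258 without 100 pM 3. Of called genes 82.6% rose, 62.1% with the block and 88.5% to 94.6% without 1 library. BCL2, CXCL12, DCDC2, KCNK5, PCED1B, SCRG1 and ZBED2 lost their calls without vehicle 1 (adjusted p 0.0537 to 0.179). PCED1B, SCRG1 and ZBED2 lost their calls without vehicle 3 (adjusted p 0.0936 to 0.107). BCL2, CXCL12, DCDC2, DOCK10, KCNK5, PCED1B, SCRG1 and ZBED2 lost their calls without 100 pM 3 (adjusted p 0.0589 to 0.181). BCL2 and SCRG1 lost their calls with that time alone (adjusted p 0.0839 to 0.0866). BCL2, CXCL12, DCDC2, PCED1B and SCRG1 lost their calls without 100 pM 1 (adjusted p 0.0526 to 0.103).

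Among the always-reported genes, FKBP5 (4.07 ± 0.41), a steroid receptor co-chaperone, GREB1 (2.001 ± 0.12), a hormone-induced coregulator, and CCND1 (2.10 ± 0.17), which encodes cyclin D1, rose at 100 pM for 6 h (edgeR adjusted p 0.000102 to 0.000768). CCND1 measured 94.4 ± 9.90 CPM in vehicle and 404 ± 55.5 CPM at 100 pM (SD, n = 2). Receptor genes were not called, with log2 fold changes of -0.51 ± 0.29 for PGR, -0.55 ± 0.19 for ESR1 and -0.56 ± 0.20 for NR3C1, and neither were MYC (0.00 ± 0.33) or MKI67 (0.12 ± 0.38). Of the 43 progestin and glucocorticoid response genes, 16 rose, 0 fell and 27 were not called (24 up and 1 down adjusted over the list alone, 27 and 1 with the block). SGK1 and PDK4 (1.99 ± 0.13), which inhibits pyruvate dehydrogenase, were among them, and the list was higher than other genes (camera adjusted p = 1.97e-19, adjusted p = 0.0395 with an estimated correlation, 0.191 when that fit also held the replicate block). Of the 20 ion and water transport genes, 4 rose, 1 fell and 15 were not called (6 up and 1 down adjusted over the list alone, 7 and 2 with the block). Camera placed ion transport genes higher (median log2 0.25, adjusted p = 0.00199, adjusted p = 0.169 with an estimated correlation). They included AQP3 (1.59 ± 0.19), a water and glycerol channel, CA12 (0.68 ± 0.09), a carbonic anhydrase, and ATP1B1 (1.94 ± 0.29), an ion pump subunit. Of the 45 genes of DNA replication and S phase, 1 rose, 0 fell and 44 were not called (the same adjusted over the list alone, 13 up and 0 down with the block). Camera placed DNA replication genes higher (median log2 0.36, adjusted p = 0.000427, adjusted p = 0.961 with an estimated correlation). The member called was GINS2 (1.81 ± 0.35), part of the replicative helicase. Of the 6 steroid receptor genes, 0 rose, 0 fell and 6 were not called (0 up and 3 down adjusted over the list alone, 0 and 3 with the block). Camera placed steroid receptor genes lower (median log2 -0.53, adjusted p = 0.00355, adjusted p = 0.169 with an estimated correlation). Blocked, camera also called steroid metabolism genes, higher (adjusted p = 0.0252, adjusted p = 0.668 with an estimated correlation). Of the 22 G1 regulators, 1 rose, 0 fell and 21 were not called (the same adjusted over the list alone, 8 up and 2 down with the block). Camera placed G1 regulators higher (median log2 0.30, adjusted p = 0.00551, adjusted p = 0.169 with an estimated correlation). Of the 18 milk and secretory differentiation genes listed, only 5 had enough counts to test. Among these 5, 1 rose, 0 fell and 4 were not called (2 up and 0 down adjusted over the list alone, 3 and 0 with the block). Camera placed milk and secretory genes higher (median log2 0.51, adjusted p = 0.00544, adjusted p = 0.169 with an estimated correlation). That list's called gene was STAT5A (3.17 ± 0.50), which relays prolactin signals. With the block the adjusted p from edgeR was 0.00691 for PGR and 0.00346 for ESR1. ATP1B1 lost its call without vehicle 1 or vehicle 3 (adjusted p 0.0567 to 0.0811). GINS2 lost its call without any 1 of the 4 libraries (adjusted p 0.0536 to 0.197).

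At 10 nM for 6 h the response was wider, with 3132 genes up and 2694 down by edgeR, 1217 and 1042 of them by more than 2-fold. The largest rises were in ZBTB7C (7.89 ± 0.54), APLN (7.86 ± 0.32), SGK1 (6.22 ± 0.60), TRIM22 (5.58 ± 0.49), CNTFR (5.20 ± 0.29), a receptor subunit for ciliary neurotrophic factor, and GPR124 (5.08 ± 0.30), an adhesion G protein-coupled receptor. CNTFR went from 0.638 ± 0.105 CPM in vehicle to 23.5 ± 6.36 CPM and GPR124 from 2.05 ± 0.622 to 69.5 ± 10.1 CPM (SD, n = 2), while at 100 pM they measured 0.561 ± 0.136 and 2.48 ± 0.961 CPM. SCRG1 was at least 93.4-fold above vehicle, where it had no count, and SEPT14, a septin, had a count ratio of 88.7 (95% counting interval 24.2 to 738). The largest falls were in SOX2 (-8.28 ± 0.68), a stem cell transcription factor, AMIGO2 (-5.64 ± 0.23), RBBP8NL (-4.53 ± 0.41), SLITRK6 (-4.47 ± 0.45) and VAV3 (-4.34 ± 0.30), a signalling adaptor. The receptors for interleukin 1, IL1R1 (-4.32 ± 0.51), and gastrin-releasing peptide, GRPR (-3.99 ± 0.44), and the dioxin-induced enzyme CYP1A1 (-4.39 ± 1.20) fell too. The 16 genes had edgeR adjusted p values of 1.79e-06 to 0.0176. The total of 5826 became 8662 with the block. CYP1A1 lost its call without vehicle 1, 10 nM 1 or 10 nM 3 (adjusted p 0.0815 to 0.136). Without vehicle 1 CYP1A1 was -2.21.

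Steroid receptor genes were lower at 10 nM for 6 h, with PGR at 1948 ± 230.0 CPM in vehicle and 541 ± 68.5 CPM at 10 nM (SD, n = 2). The log2 fold changes were -1.85 ± 0.30 for PGR, -1.89 ± 0.20 for ESR1, -1.54 ± 0.13 for the mineralocorticoid receptor gene NR3C2 and -0.62 ± 0.20 for the glucocorticoid receptor gene NR3C1 (edgeR adjusted p 4.50e-05 to 0.0356). Of the 6 steroid receptor genes, 0 rose, 5 fell and 1 was not called (the same adjusted over the list alone). Camera placed steroid receptor genes lower (median log2 -1.34, adjusted p = 0.00833, adjusted p = 0.467 with an estimated correlation). Of the 17 luminal marker genes, 1 rose, 8 fell and 8 were not called (the same adjusted over the list alone, 2 up and 12 down with the block). Camera placed luminal marker genes lower (median log2 -0.40, adjusted p = 0.0172, adjusted p = 0.615 with an estimated correlation). GATA3 (-1.64 ± 0.10) and FOXA1 (-2.66 ± 0.20), transcription factors of the luminal lineage, fell. FKBP5 (3.52 ± 0.40), GREB1 (2.25 ± 0.12), CCND1 (2.26 ± 0.17) and MYC (1.73 ± 0.33), a growth-promoting transcription factor, rose, while MKI67, a proliferation marker, was not called (-0.22 ± 0.38). Of the 43 progestin and glucocorticoid response genes, 24 rose, 5 fell and 14 were not called (the same adjusted over the list alone). Camera placed progestin and glucocorticoid response genes higher (median log2 1.03, adjusted p = 0.00605, adjusted p = 0.615 with an estimated correlation). PDK4 (3.52 ± 0.13) and TSC22D3 (3.12 ± 0.19), a leucine zipper protein induced by glucocorticoids, rose. NR3C1 lost its call without vehicle 1, vehicle 3 or 10 nM 3 (adjusted p 0.0948 to 0.213). Without 10 nM 3 NR3C1 was -0.40.

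Genes of ribosome assembly rose together at 10 nM for 6 h: of the 34 tested, 29 rose, 1 fell and 4 were not called (the same adjusted over the list alone). Camera placed ribosome biogenesis genes higher (median log2 0.80, adjusted p = 2.54e-10, adjusted p = 0.615 with an estimated correlation). NOP14 (1.31 ± 0.07) and NOP58 (1.13 ± 0.07), nucleolar proteins, had edgeR adjusted p values of 3.68e-06 to 9.20e-06, and NOP14 went from 86.7 ± 2.32 to 215 ± 7.67 CPM (SD, n = 2). Of the 22 unfolded protein response genes, 9 rose, 2 fell and 11 were not called (the same adjusted over the list alone). Camera placed unfolded protein response genes higher (median log2 0.26, adjusted p = 0.0385, adjusted p = 0.876 with an estimated correlation). They included MANF (2.15 ± 0.14), a secreted stress factor, and CREB3L2 (1.86 ± 0.14), a transcription factor of the secretory pathway. Of the 35 oxidative phosphorylation genes, 10 rose, 0 fell and 25 were not called (8 up and 0 down adjusted over the list alone). Camera placed oxidative phosphorylation genes higher (median log2 0.17, adjusted p = 0.0295, adjusted p = 0.876 with an estimated correlation). Of the 40 interferon-stimulated genes, 1 rose, 13 fell and 26 were not called (1 up and 11 down adjusted over the list alone, 3 and 22 with the block). Camera placed interferon-stimulated genes lower (median log2 -0.50, adjusted p = 0.0295, adjusted p = 0.876 with an estimated correlation). USP18 (-1.44 ± 0.22), which removes ISG15 from proteins, fell, whereas TRIM22 rose. Of the 13 replication-dependent histone genes, 0 rose, 7 fell and 6 were not called (the same adjusted over the list alone). Camera placed histone genes lower (median log2 -0.68, adjusted p = 0.0210, adjusted p = 0.876 with an estimated correlation). Near-identical histone genes lie in clusters, and the counter and strand setting were not given in the sources used here. With the block, camera also called ATF4 targets and DNA replication, heat shock, hypoxia and glycolysis genes, higher, and mitosis genes, lower (adjusted p 0.00508 to 0.0471, adjusted p 0.350 to 0.845 with an estimated correlation).

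Set directly against 100 pM at 6 h, 10 nM gave higher CNTFR (5.39 ± 0.29), SCRG1 (5.36 ± 0.33), GPR124 (4.80 ± 0.29), SEPT14 (4.79 ± 0.74) and SERPINE2 (4.54 ± 0.42), a protease inhibitor. It gave lower SOX2 (-6.53 ± 0.69), CYP1A1 (-4.71 ± 1.21), FAM83A (-3.87 ± 0.54), EHF (-3.81 ± 0.24), an epithelial transcription factor, and SLITRK6 (-3.68 ± 0.44). EHF measured 334 ± 81.3 CPM in vehicle, 637 ± 124 CPM at 100 pM and 45.2 ± 5.90 CPM at 10 nM (SD, n = 2). MYC (1.74 ± 0.33) was higher at 10 nM and PGR (-1.33 ± 0.29) and ESR1 (-1.34 ± 0.19) lower, and the difference was not called for FKBP5 (-0.55 ± 0.36), CCND1 (0.16 ± 0.16), GREB1 (0.25 ± 0.12), NR3C1 (-0.06 ± 0.20) or MKI67 (-0.34 ± 0.38). Called genes here had edgeR adjusted p values of 7.13e-06 to 0.0154. edgeR called 2795 genes up and 2332 down, 968 and 857 of them by more than 2-fold. The total of 5127 became 8231 with the block and 3281 without 100 pM 3. In the blocked edgeR fit the adjusted p was 0.00659 for FKBP5. CYP1A1 lost its call without 100 pM 1, 10 nM 1 or 10 nM 3. PGR lost its call without 10 nM 3.

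Most ribosome biogenesis and histone genes, and a part of the luminal and interferon genes, differed between the doses at 6 h. Of the 34 ribosome biogenesis genes, 28 rose, 0 fell and 6 were not called (30 up and 0 down adjusted over the list alone). Camera placed ribosome biogenesis genes higher (median log2 0.87, adjusted p = 1.94e-12, adjusted p = 0.580 with an estimated correlation). Of the 17 luminal marker genes, 0 rose, 8 fell and 9 were not called (the same adjusted over the list alone, 0 up and 13 down with the block). Camera placed luminal marker genes lower (median log2 -0.57, adjusted p = 0.00387, adjusted p = 0.580 with an estimated correlation). Of the 40 interferon-stimulated genes, 0 rose, 15 fell and 25 were not called (the same adjusted over the list alone, 2 up and 24 down with the block). Camera placed interferon-stimulated genes lower (median log2 -0.80, adjusted p = 0.00438, adjusted p = 0.970 with an estimated correlation). Of the 13 histone genes, 0 rose, 8 fell and 5 were not called (the same adjusted over the list alone). Camera placed histone genes lower (median log2 -0.72, adjusted p = 0.0159, adjusted p = 0.970 with an estimated correlation). With the block, camera also called mitosis, steroid receptor and milk genes, lower at 10 nM, and ATF4 targets and heat shock genes, higher (adjusted p 0.00540 to 0.0426, adjusted p 0.474 to 0.894 with an estimated correlation).

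**Figure D2:**
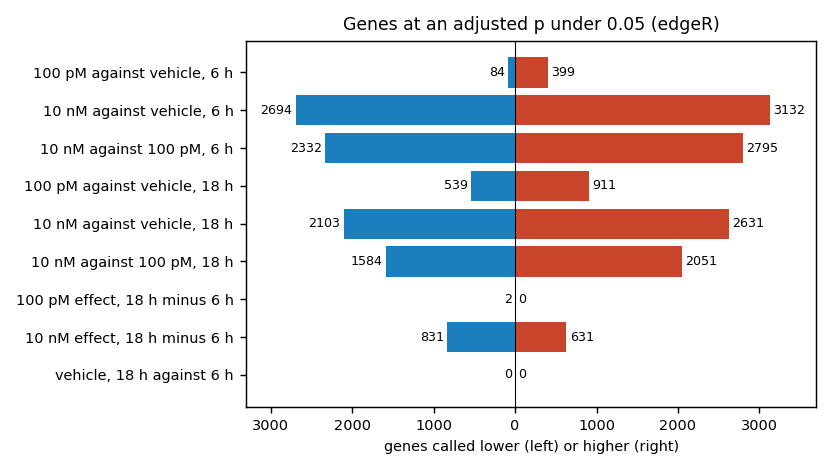
Number of genes called lower (left bars) and higher (right bars) by edgeR at an adjusted p under 0.05 in each of the 9 comparisons, out of 13872 tested.

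At 100 pM for 18 h the largest rises were in SGK1 (6.98 ± 0.56), S100P (6.32 ± 0.81), a calcium-binding protein, ZBTB7C (5.87 ± 0.53), RBP2 (5.75 ± 0.36), which carries retinol in cells, SLC25A18 (5.49 ± 0.42) and ZNF812 (4.93 ± 0.74). The secreted proteins SERPINA3 (4.79 ± 1.003), a protease inhibitor, and AZGP1 (4.77 ± 0.78), a zinc-binding glycoprotein, rose as well, AZGP1 from 16.2 ± 11.7 to 441 ± 156 CPM (SD, n = 2). The largest falls were in PLEKHH2 (-2.70 ± 0.17), SEMA6A (-2.70 ± 0.53), a semaphorin, SOX2 (-2.70 ± 0.43), KCNK5 (-2.59 ± 0.31), BCL2 (-2.43 ± 0.35), GRB14 (-2.40 ± 0.48), an adaptor that dampens insulin receptor signalling, MKX (-2.32 ± 0.22) and CBLN2 (-2.26 ± 0.26), a synapse organiser. The 16 genes had edgeR adjusted p values of 7.26e-05 to 0.0194. edgeR called 911 genes up and 539 down, 448 and 136 of them by more than 2-fold. The total of 1450 became 4728 with the block, 2203 with DESeq2, 655 with that time alone, 512 without vehicle 1, 630 without vehicle 3, 845 without 100 pM 1 and 713 without 100 pM 3. The share of called genes that rose was 62.8%, 50.02% with the block and 72.8% with that time alone. ZNF812 lost its call without vehicle 1 (adjusted p 0.0524). SERPINA3 lost its call without 100 pM 1 or vehicle 3 and with that time alone (adjusted p 0.0562 to 0.102). SEMA6A lost its call without 100 pM 1, 100 pM 3 or vehicle 3 (adjusted p 0.0519 to 0.0924). GRB14 lost its call without 100 pM 1, 100 pM 3 or vehicle 1 (adjusted p 0.0548 to 0.108).

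Genes of DNA replication rose at 100 pM for 18 h: of the 45 tested, 30 rose, 0 fell and 15 were not called (44 up and 0 down adjusted over the list alone). Camera placed DNA replication genes higher (median log2 1.48, adjusted p = 1.11e-20, adjusted p = 0.521 with an estimated correlation). GINS2 (2.97 ± 0.36) went from 19.7 ± 5.66 to 155 ± 37.3 CPM (SD, n = 2), and the histone mRNA binder SLBP (0.76 ± 0.12) rose too. Of the 52 genes of mitosis and G2/M, 2 rose, 0 fell and 50 were not called (0 up and 0 down adjusted over the list alone, 45 and 0 with the block). Camera placed mitosis genes higher (median log2 0.999, adjusted p = 3.14e-10, adjusted p = 0.641 with an estimated correlation). The members called were MKI67 (1.65 ± 0.39) and MYBL2 (2.09 ± 0.53), a transcription factor of dividing cells. Of the 22 G1 regulators, 9 rose, 2 fell and 11 were not called (13 up and 2 down adjusted over the list alone, 15 and 3 with the block). Camera placed G1 regulators higher (median log2 0.85, adjusted p = 3.71e-05, adjusted p = 0.130 with an estimated correlation). CCND1 (1.68 ± 0.17) and the kinase inhibitor gene CDKN1B (0.64 ± 0.10) rose. Of the 43 genes of cytosolic ribosomal proteins, 0 rose, 0 fell and 43 were not called (the same adjusted over the list alone, 0 up and 34 down with the block). Camera placed ribosomal protein genes lower (median log2 -0.26, adjusted p = 7.65e-08, adjusted p = 0.662 with an estimated correlation). CDKN1B, MKI67, MYBL2 and SLBP lost their calls without vehicle 1 (adjusted p 0.0533 to 0.217). MKI67 and MYBL2 lost their calls without vehicle 3 or 100 pM 3 and with that time alone (adjusted p 0.0607 to 0.164). MYBL2 lost its call without 100 pM 1 and without the low-count filter (adjusted p 0.0508 to 0.0660).

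Hormone response genes were again higher at 100 pM for 18 h, with FKBP5 (4.49 ± 0.42) and GREB1 (1.56 ± 0.12) called. Of the 43 progestin and glucocorticoid response genes, 20 rose, 0 fell and 23 were not called (28 up and 2 down adjusted over the list alone, 32 and 2 with the block). Camera placed progestin and glucocorticoid response genes higher (median log2 0.83, adjusted p = 9.20e-14, adjusted p = 0.0888 with an estimated correlation). PDK4 (1.86 ± 0.13) and HSD11B2 (2.96 ± 0.23), which inactivates cortisol, rose. Of the 6 steroid receptor genes, 0 rose, 4 fell and 2 were not called (0 up and 5 down adjusted over the list alone). Camera placed steroid receptor genes lower (median log2 -0.67, adjusted p = 0.00172, adjusted p = 0.137 with an estimated correlation). The log2 fold changes were -1.66 ± 0.29 for PGR, -0.85 ± 0.19 for ESR1 and -0.68 ± 0.13 for NR3C2, and NR3C1 (-0.56 ± 0.20) and MYC (-0.11 ± 0.33) were not called. Of the 20 ion and water transport genes, 8 rose, 1 fell and 11 were not called (9 up and 1 down adjusted over the list alone, 12 and 5 with the block). Camera placed ion transport genes higher (median log2 0.60, adjusted p = 0.000924, adjusted p = 0.208 with an estimated correlation). AQP3 (3.74 ± 0.20) went from 5.25 ± 1.07 to 70.4 ± 15.2 CPM (SD, n = 2), and CA12 (1.16 ± 0.09) rose. Of the 5 milk and secretory differentiation genes, 2 rose, 0 fell and 3 were not called (3 up and 0 down adjusted over the list alone). Camera placed milk and secretory genes higher (median log2 0.84, adjusted p = 0.0123, adjusted p = 0.319 with an estimated correlation). STAT5A (3.0001 ± 0.49) and ELF5 (0.84 ± 0.15), a factor of alveolar cell fate, were the members called. Of the 17 steroid metabolism genes, 3 rose, 0 fell and 14 were not called (4 up and 0 down adjusted over the list alone, 5 and 1 with the block). Camera placed steroid metabolism genes higher (median log2 0.21, adjusted p = 0.0433, adjusted p = 0.478 with an estimated correlation). The members called were HSD11B2, UGT2B11, whose close copies share most of its sequence, with a count ratio of 146 (95% counting interval 25.9 to 5816), and HSD17B2, which oxidises estradiol, with 15.4 (4.95 to 77.3). The block took the edgeR adjusted p to 0.0297 for NR3C1. HSD17B2, NR3C2 and PGR lost their calls with that time alone (adjusted p 0.0520 to 0.0836). ELF5, ESR1, HSD17B2, NR3C2, PGR and UGT2B11 lost their calls without vehicle 1 (adjusted p 0.0642 to 0.168). ESR1, HSD17B2, NR3C2 and PGR lost their calls without 100 pM 3 (adjusted p 0.0614 to 0.124). ESR1, HSD17B2, NR3C2 and UGT2B11 lost their calls without vehicle 3 (adjusted p 0.0615 to 0.129). ESR1 lost its call without 100 pM 1 (adjusted p 0.0977).

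Metabolic and stress genes moved in part at 100 pM for 18 h. Of the 27 fatty acid synthesis and lipid storage genes, 5 rose, 0 fell and 22 were not called (6 up and 0 down adjusted over the list alone, 15 and 1 with the block). Camera placed fatty acid genes higher (median log2 0.41, adjusted p = 9.94e-05, adjusted p = 0.208 with an estimated correlation). ELOVL5 (0.70 ± 0.10) and ELOVL6 (1.11 ± 0.16), which lengthen fatty acids, PLIN2 (0.70 ± 0.10), which coats lipid droplets, and FASN (1.73 ± 0.37), the fatty acid synthase, rose. Of the 19 hypoxia response genes, 7 rose, 0 fell and 12 were not called (10 up and 1 down adjusted over the list alone, 11 and 2 with the block). Camera placed hypoxia response genes higher (median log2 0.61, adjusted p = 0.000436, adjusted p = 0.522 with an estimated correlation). Of the 25 glycolysis and glucose uptake genes, 3 rose, 1 fell and 21 were not called (4 up and 1 down adjusted over the list alone, 14 and 2 with the block). Camera placed glycolysis genes higher (median log2 0.34, adjusted p = 0.00987, adjusted p = 0.741 with an estimated correlation). Of the 22 unfolded protein response genes, 2 rose, 0 fell and 20 were not called (5 up and 0 down adjusted over the list alone, 8 and 0 with the block). Camera placed unfolded protein response genes higher (median log2 0.18, adjusted p = 0.00172, adjusted p = 0.548 with an estimated correlation). The pair called were CREB3L2 (0.86 ± 0.14) and XBP1 (1.30 ± 0.25), transcription factors of that response. Of the 25 ATF4 target genes, 3 rose, 0 fell and 22 were not called (the same adjusted over the list alone, 11 up and 0 down with the block). Camera placed ATF4 target genes higher (median log2 0.17, adjusted p = 0.0433, adjusted p = 0.810 with an estimated correlation). STC2 (1.81 ± 0.25), VLDLR (1.15 ± 0.16) and PHGDH (1.04 ± 0.19), which opens serine synthesis, were the members called. With the block, camera also called mitochondrially encoded genes, lower, and cholesterol synthesis genes, higher (adjusted p 0.00200 to 0.00780, adjusted p 0.488 to 0.579 with an estimated correlation). FASN lost its call without any 1 of the 4 libraries (adjusted p 0.0528 to 0.144). CREB3L2 lost its call without vehicle 1 (adjusted p 0.0568). PHGDH and XBP1 lost their calls without 100 pM 3 or vehicle 1 (adjusted p 0.0647 to 0.112).

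At 10 nM for 18 h the largest rises were in C1orf168 (7.04 ± 0.71), ZBTB7C (6.92 ± 0.53), SGK1 (6.84 ± 0.56), ACOT6 (6.71 ± 0.80), an acyl-CoA thioesterase, GPR124 (6.44 ± 0.31) and SLPI (6.08 ± 0.47), a secreted protease inhibitor. SLPI went from 0.565 ± 0.110 to 38.5 ± 0.662 CPM and GPR124 from 2.81 ± 0.142 to 245 ± 43.5 CPM (SD, n = 2). SEPT14 had no count in vehicle and was at least 436.6-fold higher, and SCRG1 had a count ratio of 1895 (95% counting interval 339.8 to 74908). The largest falls were in SOX2 (-5.42 ± 0.53), CBLN2 (-5.24 ± 0.32), IL1R1 (-4.49 ± 0.51), ENTPD3 (-4.45 ± 0.35), an ectonucleotidase, TGFB2 (-4.38 ± 0.24), a transforming growth factor, ID1 (-4.32 ± 0.72), an inhibitor of differentiation factors, ROBO2 (-4.32 ± 0.20), a guidance receptor, and FGF12 (-4.30 ± 0.14). The 16 genes had edgeR adjusted p values of 1.08e-06 to 0.00201. edgeR called 2631 genes up and 2103 down, 1183 and 811 of them by more than 2-fold. The total of 4734 became 7767 with the block.

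Lipid synthesis genes rose at 10 nM for 18 h: of the 24 tested genes of cholesterol synthesis, 16 rose, 0 fell and 8 were not called (17 up and 0 down adjusted over the list alone). Camera placed cholesterol synthesis genes higher (median log2 1.19, adjusted p = 0.000178, adjusted p = 0.758 with an estimated correlation). They included PMVK (1.77 ± 0.12) of the mevalonate pathway, from 49.1 ± 4.31 to 167 ± 13.2 CPM (SD, n = 2), and EBP (1.30 ± 0.20), a late enzyme of sterol synthesis. Of the 27 fatty acid synthesis and lipid storage genes, 17 rose, 1 fell and 9 were not called (the same adjusted over the list alone). Camera placed fatty acid genes higher (median log2 1.12, adjusted p = 0.000534, adjusted p = 0.442 with an estimated correlation). ELOVL5 (1.43 ± 0.10), which lengthens fatty acids, and ACACA (1.30 ± 0.10), the carboxylase that commits carbon to them, rose. Of the 35 oxidative phosphorylation genes, 13 rose, 0 fell and 22 were not called (the same adjusted over the list alone). Camera placed oxidative phosphorylation genes higher (median log2 0.18, adjusted p = 0.000534, adjusted p = 0.758 with an estimated correlation). Of the 22 unfolded protein response genes, 8 rose, 1 fell and 13 were not called (10 up and 1 down adjusted over the list alone, 13 and 2 with the block). Camera placed unfolded protein response genes higher (median log2 0.32, adjusted p = 0.00957, adjusted p = 0.758 with an estimated correlation). Of the 45 genes of DNA replication and S phase, 3 rose, 0 fell and 42 were not called (1 up and 0 down adjusted over the list alone, 34 and 0 with the block). Camera placed DNA replication genes higher (median log2 0.68, adjusted p = 0.00957, adjusted p = 0.911 with an estimated correlation). GINS2 (2.68 ± 0.36), POLE2 (1.44 ± 0.39) and SLBP (0.43 ± 0.12) were the members called, and MKI67 (0.85 ± 0.38) was not called. With the block the adjusted p from edgeR was 0.00321 for MKI67. POLE2 and SLBP lost their calls without vehicle 1, vehicle 3 or 10 nM 3 (adjusted p 0.0517 to 0.169). SLBP lost its call with that time alone (adjusted p 0.0737). MKI67 gained a call without 10 nM 1 (adjusted p 0.0413). Without 10 nM 3 POLE2 was 0.89.

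Part of the luminal, interferon and clock genes fell at 10 nM for 18 h. Of the 17 luminal marker genes, 1 rose, 8 fell and 8 were not called (the same adjusted over the list alone, 3 up and 13 down with the block). Camera placed luminal marker genes lower (median log2 -0.88, adjusted p = 0.00102, adjusted p = 0.411 with an estimated correlation). GATA3 (-1.56 ± 0.10) and KRT18 (-1.35 ± 0.11) fell, KRT18 from 1412 ± 79.4 to 555 ± 75.9 CPM (SD, n = 2). Of the 40 interferon-stimulated genes, 1 rose, 16 fell and 23 were not called (the same adjusted over the list alone, 2 up and 25 down with the block). Camera placed interferon-stimulated genes lower (median log2 -0.72, adjusted p = 0.00429, adjusted p = 0.911 with an estimated correlation). OAS2 (-3.81 ± 0.59), an enzyme that senses viral RNA, fell while TRIM22 (5.30 ± 0.46) rose. Of the 20 circadian clock genes, 1 rose, 8 fell and 11 were not called (the same adjusted over the list alone, 3 up and 13 down with the block). Camera placed circadian clock genes lower (median log2 -0.36, adjusted p = 0.0321, adjusted p = 0.758 with an estimated correlation). TEF (-1.01 ± 0.10) and HLF (-2.02 ± 0.21), clock output factors, fell. Of the 43 progestin and glucocorticoid response genes, 25 rose, 5 fell and 13 were not called (28 up and 5 down adjusted over the list alone). Camera placed progestin and glucocorticoid response genes higher (median log2 1.34, adjusted p = 4.35e-05, adjusted p = 0.411 with an estimated correlation). PDK4 (3.92 ± 0.14) and HSD11B2 (4.57 ± 0.24) rose. FKBP5 (4.64 ± 0.42), GREB1 (2.72 ± 0.13), CCND1 (1.35 ± 0.17) and MYC (0.99 ± 0.33) rose, PGR (-1.92 ± 0.30) and ESR1 (-0.88 ± 0.19) fell, and NR3C1 (-0.22 ± 0.20) was not called. Keratin genes have processed copies elsewhere in the genome, and how shared reads were counted is not given in the sources used here. With the block, camera also called G1 regulators, mitosis genes and ATF4 targets, higher (adjusted p 0.00185 to 0.0341, adjusted p 0.508 to 0.884 with an estimated correlation). MYC lost its call without 10 nM 1, vehicle 1 or vehicle 3, without the low-count filter and with that time alone (adjusted p 0.0593 to 0.250). ESR1 lost its call without 10 nM 1 (adjusted p 0.0581). Without 10 nM 1 MYC was 0.64.

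Set directly against 100 pM at 18 h, 10 nM gave higher SEPT14 (7.66 ± 0.65), GPR124 (6.82 ± 0.31), CNTFR (6.002 ± 0.31), SCRG1 (5.996 ± 0.30) and ELFN2 (5.73 ± 0.78). Lower at 10 nM were C1orf64 (-4.10 ± 0.56), the interferon-induced RNA sensor OAS2 (-3.44 ± 0.58), the fatty acid hydroxylase gene CYP4Z1 (-3.40 ± 0.49), PIP (-3.19 ± 0.84), a secreted protein of apocrine glands, and AQP3 (-3.16 ± 0.19). AQP3 measured 70.4 ± 15.2 CPM at 100 pM and 7.84 ± 1.07 CPM at 10 nM (SD, n = 2). GREB1 (1.16 ± 0.12) and MYC (1.10 ± 0.33) were higher at 10 nM, and no difference was called for PGR (-0.26 ± 0.29), ESR1 (-0.03 ± 0.19), NR3C1 (0.34 ± 0.20), FKBP5 (0.15 ± 0.36), CCND1 (-0.34 ± 0.16) or MKI67 (-0.80 ± 0.38). Called genes here had edgeR adjusted p values of 1.26e-05 to 0.0390. edgeR called 2051 genes up and 1584 down, 813 and 566 of them by more than 2-fold. The total of 3635 became 6958 with the block, 2376 without 100 pM 3 and 2286 without 10 nM 1. In the blocked edgeR fit the adjusted p was 0.0397 for CCND1 and 0.00360 for MKI67. MYC and PIP lost their calls without 100 pM 3 or 10 nM 1 (adjusted p 0.115 to 0.225). MYC lost its call without the low-count filter and with that time alone (adjusted p 0.0514 to 0.0735). CCND1 gained a call without 100 pM 3 (adjusted p 0.0341). MKI67 gained a call without 10 nM 3 (adjusted p 0.0490).

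At 18 h, 5 of the 45 replication genes tested were called lower at 10 nM than at 100 pM, and 43 with the block. In both fits 0 rose, and 40 were not called unblocked (0 up and 0 down adjusted over the list alone). Camera placed the list lower (median log2 -0.86, adjusted p = 2.84e-07, adjusted p = 0.952 with an estimated correlation). DBF4 (-0.69 ± 0.20), DNMT1 (-0.66 ± 0.18), FEN1 (-1.10 ± 0.32) and POLD1 (-0.73 ± 0.16) were among those called. Of the 52 genes of mitosis and G2/M, 0 rose, 3 fell and 49 were not called (the same adjusted over the list alone, 1 up and 35 down with the block). Camera placed mitosis genes lower (median log2 -0.62, adjusted p = 9.62e-05, adjusted p = 0.952 with an estimated correlation). BUB3 (-1.07 ± 0.13), ASPM (-1.11 ± 0.18) and ECT2 (-0.997 ± 0.21) were the members called. Of the 24 cholesterol synthesis genes, 8 rose, 0 fell and 16 were not called (the same adjusted over the list alone, 21 up and 0 down with the block). Camera placed cholesterol synthesis genes higher (median log2 0.83, adjusted p = 0.000280, adjusted p = 0.933 with an estimated correlation). Of the 35 oxidative phosphorylation genes, 15 rose, 0 fell and 20 were not called (21 up and 0 down adjusted over the list alone, 24 and 0 with the block). Camera placed oxidative phosphorylation genes higher (median log2 0.30, adjusted p = 8.92e-06, adjusted p = 0.933 with an estimated correlation). DBF4, DNMT1 and FEN1 lost their calls with that time alone (adjusted p 0.0776 to 0.101). DBF4, DNMT1, ECT2, FEN1 and POLD1 lost their calls without 100 pM 3 or 10 nM 1. Without 100 pM 3 the values were DBF4 -0.41 and DNMT1 -0.41. Without 10 nM 1 FEN1 was -0.71. Without 10 nM 3 FEN1 was -1.66.

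Between the doses at 18 h a few ribosomal protein genes were called higher at 10 nM, and part of the luminal, interferon and clock genes lower. Of the 43 ribosomal protein genes, 3 rose, 0 fell and 40 were not called (0 up and 0 down adjusted over the list alone, 23 and 0 with the block). Camera placed ribosomal protein genes higher (median log2 0.19, adjusted p = 0.00281, adjusted p = 0.952 with an estimated correlation). The members called were RPS14 (0.45 ± 0.12), RPS19 (0.32 ± 0.10) and RPS24 (0.33 ± 0.10), whose transcripts have many processed copies. Of the 17 luminal marker genes, 1 rose, 8 fell and 8 were not called (the same adjusted over the list alone, 3 up and 13 down with the block). Camera placed luminal marker genes lower (median log2 -0.93, adjusted p = 0.000280, adjusted p = 0.560 with an estimated correlation). Of the 40 interferon-stimulated genes, 0 rose, 7 fell and 33 were not called (0 up and 4 down adjusted over the list alone, 3 and 20 with the block). Camera placed interferon-stimulated genes lower (median log2 -0.44, adjusted p = 0.00467, adjusted p = 0.952 with an estimated correlation). OAS2 and OAS3 (-1.69 ± 0.36) were lower. Of the 20 circadian clock genes, 1 rose, 4 fell and 15 were not called (the same adjusted over the list alone, 1 up and 9 down with the block). Camera placed circadian clock genes lower (median log2 -0.51, adjusted p = 0.0286, adjusted p = 0.933 with an estimated correlation). BHLHE40 (-1.39 ± 0.11), HLF (-1.29 ± 0.22), PER2 (-0.61 ± 0.12) and CRY2 (-0.67 ± 0.14) were lower. Blocked, camera also called fatty acid genes, higher (adjusted p = 0.0366, adjusted p = 0.785 with an estimated correlation). RPS14, RPS19 and RPS24 lost their calls with that time alone (adjusted p 0.0600 to 0.137). CRY2, RPS14, RPS19 and RPS24 lost their calls without 100 pM 3 (adjusted p 0.0642 to 0.246). CRY2, OAS3, RPS14, RPS19 and RPS24 lost their calls without 10 nM 1 (adjusted p 0.0684 to 0.236). RPS19 lost its call without 10 nM 3 and with RLE factors (adjusted p 0.0519 to 0.0836). RPS19 and RPS24 lost their calls without the low-count filter (adjusted p 0.0770 to 0.0781).

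**Figure D3:**
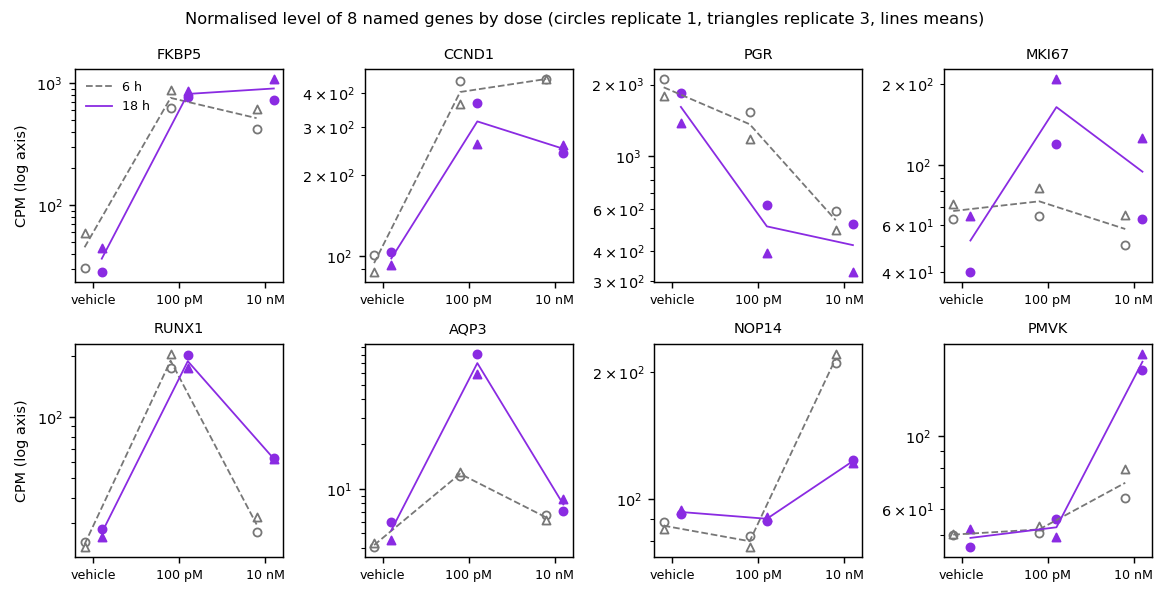
Normalised level in CPM (log axis) of 8 named genes by dose, with 1 symbol per library, circles for replicate 1, triangles for replicate 3, and lines through the group means at 6 h (dashed) and 18 h (solid). RUNX1 and AQP3 were highest at 100 pM at both times, and NOP14 stood highest at 10 nM for 6 h.

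Between the times edgeR called 2 genes for a different effect of 100 pM. The 2 were MAML2 (-1.22 ± 0.11), a Notch coactivator, and NPNT (-1.01 ± 0.10), an extracellular matrix protein, lower at 18 h relative to 6 h (edgeR adjusted p = 0.0333 and 0.0416). MAML2 measured 35.5 ± 1.37 CPM at 6 h and 14.8 ± 0.720 CPM at 18 h under 100 pM, against 48.9 ± 2.99 and 47.7 ± 1.57 CPM in vehicle (SD, n = 2). PGR (-1.15 ± 0.41), MKI67 (1.53 ± 0.54), CCND1 (-0.42 ± 0.23), GREB1 (-0.44 ± 0.17), FKBP5 (0.42 ± 0.51), ESR1 (-0.30 ± 0.27), MYC (-0.10 ± 0.46) and NR3C1 (0.00 ± 0.28) were not called. By list, camera called 10 of the 35 tested, with larger 18 h effects on DNA replication and S phase (median 1.10, adjusted p = 7.87e-21), mitosis (median 0.93, adjusted p = 7.13e-12), G1 regulators (median 0.42, adjusted p = 0.0133), hypoxia response (median 0.30, adjusted p = 0.0181), fatty acid synthesis (median 0.25, adjusted p = 0.000414), glycolysis (median 0.20, adjusted p = 0.0427) and the unfolded protein response (median 0.13, adjusted p = 0.0364). Camera placed the 18 h effects lower for cytosolic ribosomal proteins (median -0.30, adjusted p = 6.14e-14), estrogen response genes (median -0.20, adjusted p = 0.0364) and oxidative phosphorylation (median -0.10, adjusted p = 0.0364). For these 10 lists the adjusted p = 0.417 to 0.742 with an estimated correlation, and none of their members was called. Adjusted over the list alone, 1 fatty acid gene and 1 estrogen response gene were up and 5 estrogen response genes down. With the block 39 of the 45 S phase genes and 17 of the 52 mitosis genes were called up. Camera called there also cholesterol synthesis, ATF4 and NF-kB genes, higher, and mitochondrially encoded genes, lower (adjusted p 3.17e-05 to 0.0117, adjusted p 0.507 to 0.581 with an estimated correlation). The total of 2 genes became 777 with the block, 107 with DESeq2, 5 without the low-count filter, 6 with the stricter low-count filter, 1 with RLE factors and 0 without any 1 of the 8 libraries. The block took the edgeR adjusted p to 0.00285 for PGR and 0.0110 for MKI67. MAML2 and NPNT lost their calls without any 1 of the 8 libraries. NPNT lost its call with RLE factors (adjusted p 0.0591).

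The effect of 10 nM changed more between the times, with 631 genes up and 831 down in the 18 h effect relative to the 6 h effect (edgeR), 252 and 237 of them by more than 2-fold. Genes whose 18 h effect was higher included FAM83A (5.12 ± 0.68), SLPI (3.04 ± 0.66), CLDN8 (2.92 ± 0.77), a tight junction claudin, CSRNP3 (2.70 ± 0.34) and RNF43 (2.62 ± 0.40), a ubiquitin ligase that restrains Wnt receptors. Those whose effect was lower included CTNND2 (-3.53 ± 0.80), a catenin, FGF12 (-3.49 ± 0.18), ENTPD3 (-3.26 ± 0.44), BCAS1 (-3.02 ± 0.18) and TPM4 (-2.96 ± 0.50), a tropomyosin. BCAS1 measured 82.7 ± 2.98 CPM at 6 h and 12.03 ± 2.53 CPM at 18 h under 10 nM, against 179 ± 13.5 and 212 ± 4.63 CPM in vehicle (SD, n = 2). ESR1 (1.01 ± 0.27) was called upward and CCND1 (-0.91 ± 0.23) downward, and PGR (-0.07 ± 0.41), NR3C1 (0.39 ± 0.28), FKBP5 (1.12 ± 0.52), GREB1 (0.47 ± 0.17), MYC (-0.74 ± 0.46) and MKI67 (1.07 ± 0.53) were not called. Called genes here had edgeR adjusted p values of 0.000201 to 0.0484. The total of 1462 became 4863 with the block, 2298 with DESeq2, 645 without vehicle 1 at 6 h, 492 without vehicle 3 at 6 h, 610 without 10 nM 1 at 6 h, 791 without 10 nM 3 at 6 h, 467 without vehicle 1 at 18 h, 631 without vehicle 3 at 18 h, 860 without 10 nM 1 at 18 h and 739 without 10 nM 3 at 18 h. With the block the adjusted p from edgeR was 0.00295 for FKBP5, 0.0272 for GREB1, 0.0312 for MYC and 0.00984 for MKI67. CCND1, CLDN8, CTNND2, ESR1 and SLPI lost their calls without vehicle 1 at 6 h, 10 nM 1 at 6 h, vehicle 1 at 18 h, 10 nM 1 at 18 h or 10 nM 3 at 18 h. CCND1 and SLPI lost their calls without 10 nM 3 at 6 h. CCND1, ESR1 and SLPI lost their calls without vehicle 3 at 18 h. CLDN8 and ESR1 lost their calls without the low-count filter (adjusted p 0.0536 to 0.0602). CCND1, CLDN8, CTNND2 and ESR1 lost their calls without vehicle 3 at 6 h.

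Ribosome biogenesis genes had a smaller response to 10 nM at 18 h than at 6 h: of the 34, 0 rose, 19 fell and 15 were not called (0 up and 24 down adjusted over the list alone). Camera placed ribosome biogenesis genes lower (median log2 -0.84, adjusted p = 5.67e-14, adjusted p = 0.590 with an estimated correlation). NOP14 (-0.91 ± 0.10) and NOP2 (-1.12 ± 0.12) were among them. Of the 31 genes of actin, focal adhesion and motility, 0 rose, 9 fell and 22 were not called (0 up and 12 down adjusted over the list alone, 1 and 15 with the block). Camera placed actin and adhesion genes lower (median log2 -0.55, adjusted p = 5.04e-05, adjusted p = 0.662 with an estimated correlation). PALLD (-1.51 ± 0.16) and LIMA1 (-0.98 ± 0.11), proteins of stress fibres, were among them. Of the 24 cholesterol synthesis genes, 2 rose, 0 fell and 22 were not called (the same adjusted over the list alone, 18 up and 0 down with the block). Camera placed cholesterol synthesis genes higher (median log2 0.77, adjusted p = 0.000559, adjusted p = 0.908 with an estimated correlation). PMVK (1.25 ± 0.17) and STARD4 (1.78 ± 0.46), a sterol carrier, were the members called. Of the 27 fatty acid synthesis and lipid storage genes, 4 rose, 0 fell and 23 were not called (5 up and 0 down adjusted over the list alone, 15 and 0 with the block). Camera placed fatty acid genes higher (median log2 0.56, adjusted p = 0.00151, adjusted p = 0.590 with an estimated correlation). ACSL3 (0.99 ± 0.18), ACACB (1.74 ± 0.42), ELOVL5 (0.73 ± 0.14) and ELOVL6 (1.39 ± 0.22) were the members called. Of the 52 genes of mitosis and G2/M, 1 rose, 0 fell and 51 were not called (0 up and 0 down adjusted over the list alone, 22 and 1 with the block). Camera placed mitosis genes higher (median log2 0.80, adjusted p = 0.01005, adjusted p = 0.978 with an estimated correlation). The member called was ASPM (0.98 ± 0.25), a spindle pole protein. Blocked, camera also called heat shock genes, lower, and DNA replication genes, higher (adjusted p = 0.0347, adjusted p = 0.851 with an estimated correlation). ACACB, ASPM, ELOVL5 and STARD4 lost their calls without vehicle 1 at 6 h, vehicle 3 at 6 h, 10 nM 1 at 6 h, vehicle 1 at 18 h or 10 nM 3 at 18 h. ACACB, ASPM and STARD4 lost their calls without 10 nM 3 at 6 h or vehicle 3 at 18 h. STARD4 lost its call without 10 nM 1 at 18 h. ASPM lost its call without the low-count filter (adjusted p 0.0513). Without 10 nM 3 at 18 h ASPM was 0.63.

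In vehicle, edgeR and DESeq2 called no gene between 18 h and 6 h. By edgeR 178 of 13872 had an unadjusted p under 0.05, a share below 0.05, and 1343 with the block. So 0 unblocked calls cannot show that time had no effect. Log2 differences were PGR -0.27 ± 0.29, ESR1 -0.33 ± 0.19, NR3C1 -0.19 ± 0.20, FKBP5 -0.31 ± 0.37, GREB1 -0.32 ± 0.12, CCND1 0.06 ± 0.17, MYC 0.24 ± 0.33 and MKI67 -0.36 ± 0.38. By list, camera placed immediate-early genes (median 0.24, adjusted p = 3.54e-05), interferon-stimulated genes (median 0.30, adjusted p = 1.90e-07), basal and squamous keratins (median 0.55, adjusted p = 0.000181), actin and adhesion genes (median 0.09, adjusted p = 0.00505) and ribosome biogenesis genes (median 0.05, adjusted p = 0.0409) higher at 18 h and mitosis genes (median -0.25, adjusted p = 0.00229) and steroid receptor genes (median -0.19, adjusted p = 0.0409) lower. These 7 lists had adjusted p = 0.549 to 0.906 with an estimated correlation and 0 members called, over all genes or adjusted over the list alone. With the block edgeR called 4 genes, ICAM1, ATF3, MTRNR2L12 and DDIT3 (chosen after their values were seen), all higher at 18 h. In that fit camera called 15 lists, the 8 more being ATF4, NF-kB, cholesterol synthesis, clock and mesenchymal genes, higher, and DNA replication, histone and mitochondrially encoded genes, lower (adjusted p 4.43e-07 to 0.0370, adjusted p 0.162 to 0.705 for the 15 with an estimated correlation).

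**Figure D4:**
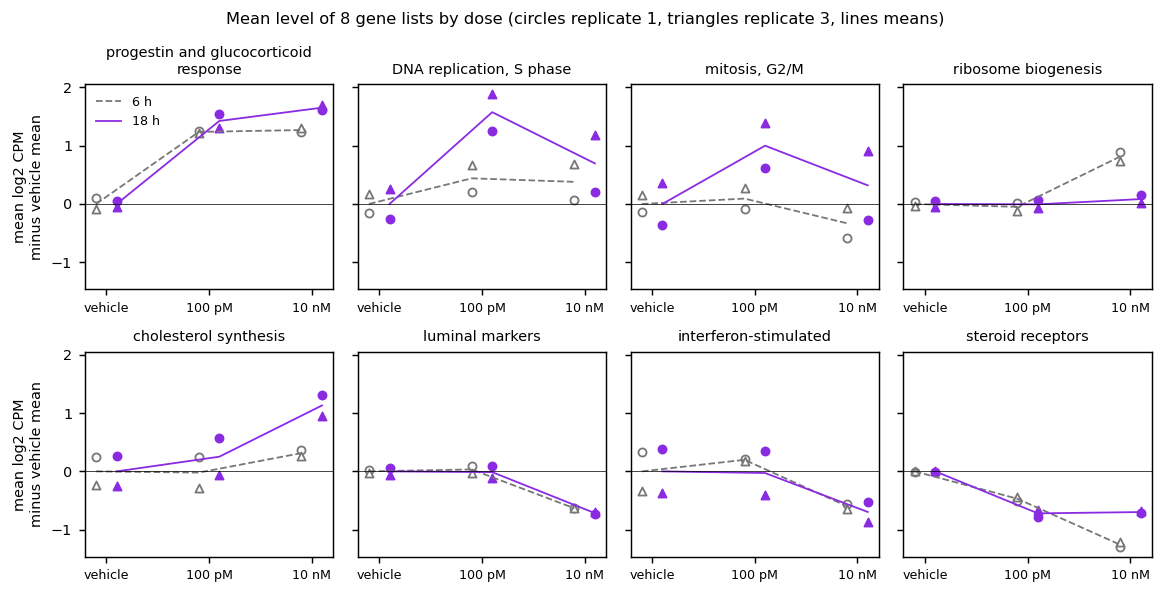
Mean log2 CPM of 8 gene lists in each library minus the mean of the vehicle libraries of the same time, by dose, with circles for replicate 1, triangles for replicate 3 and lines through group means at 6 h (dashed) and 18 h (solid).

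Some genes rose at 100 pM and were lower again at 10 nM. At 6 h the 5 with the largest smaller step were RUNX1 (3.003 ± 0.13 and -2.68 ± 0.12), a transcription factor, PLEKHD1 (2.53 ± 0.37 and -2.64 ± 0.37), RANBP3L (4.43 ± 0.76 and -2.45 ± 0.67), EPGN (2.45 ± 0.26 and -2.24 ± 0.25), a ligand of the epidermal growth factor receptor, and CLIC6 (2.57 ± 0.40 and -2.11 ± 0.39), given as the step from vehicle to 100 pM and the step from 100 pM to 10 nM. RUNX1 measured 23.6 ± 1.04 CPM in vehicle, 189.5 ± 21.2 CPM at 100 pM and 29.6 ± 3.46 CPM at 10 nM (SD, n = 2). At 18 h they were AQP3 (3.74 ± 0.20 and -3.16 ± 0.19), CYP4Z1 (3.71 ± 0.49 and -3.40 ± 0.49), SERHL2 (2.84 ± 0.53 and -2.45 ± 0.52), PLEKHD1 (3.26 ± 0.38 and -2.26 ± 0.36) and ZNF812 (4.93 ± 0.74 and -2.01 ± 0.64). CYP4Z1 and SERHL2 have close copies in the genome. PLEKHD1 and RANBP3L lost their calls without vehicle 1 at 6 h (adjusted p 0.0720 to 0.125). CLIC6 and RANBP3L lost their calls without vehicle 3 at 6 h (adjusted p 0.0639 to 0.0911). RANBP3L lost its call without 100 pM 3 at 6 h or 10 nM 1 at 6 h (adjusted p 0.0701 to 0.121). SERHL2 and ZNF812 lost their calls without vehicle 1 at 18 h, 100 pM 3 at 18 h or 10 nM 1 at 18 h (adjusted p 0.0524 to 0.229). ZNF812 lost its call without 100 pM 1 at 18 h or 10 nM 3 at 18 h and without the low-count filter (adjusted p 0.0577 to 0.0727).

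At 6 h, 181 genes were opposed (called at 100 pM against vehicle and in the other direction at 10 nM against 100 pM), 161 of them up and 20 down at 100 pM, and 145 were graded (called in the same direction in both steps), 97 up and 48 down. At 18 h, 409 were opposed (286 up and 123 down at 100 pM) and 310 graded (160 and 150). Of the opposed genes 31 at 6 h and 65 at 18 h crossed vehicle with a call on the far side, 97 and 285 were not called at 10 nM against vehicle, and 53 and 59 were called on the same side. Another 157 and 731 of the genes called at 100 pM were not called between the doses. Opposed at both times in the same direction were 87 genes, against 3.50 for independent lists. With the block the opposed genes numbered 630 and 1702 and the graded genes 686 and 1221, and DESeq2 gave 285 and 623 opposed and 269 and 480 graded. The 6 h opposed count was 75 without vehicle 1, 93 without vehicle 3, 118 without 100 pM 1 and 85 without 100 pM 3. The 6 h graded count was 58 without vehicle 1, 71 without vehicle 3, 69 without 100 pM 1 and 62 without 100 pM 3. The 18 h opposed count was 159 without vehicle 1, 194 without vehicle 3, 242 without 100 pM 1, 185 without 100 pM 3 and 249 without 10 nM 1. The 18 h graded count was 129 without vehicle 1, 152 without vehicle 3, 150 without 100 pM 1 and 136 without 100 pM 3. From the 6 libraries of 1 time alone, the graded count was 95 at 6 h and 149 at 18 h, and the 18 h opposed count was 168.

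The ratio of the 100 pM to the 10 nM response used median log2 folds, in genes called for 10 nM at the other time. At 6 h the ratio was 0.123 for the 2631 genes that rose at 18 h (95% resampling interval 0.110 to 0.135, replicates 0.157 and 0.101) and 0.224 for the 2103 that fell (0.211 to 0.242, replicates 0.234 and 0.225). At 18 h it was 0.202 for the 3132 genes that rose at 6 h (0.182 to 0.227, replicates 0.221 and 0.166) and 0.436 for the 2694 that fell (0.406 to 0.470, replicates 0.440 and 0.441). The intervals resample genes and cover genes only, which are not independent replicates. With the block the ratio for genes that fell was 0.233 at 6 h and 0.467 at 18 h. Taking genes called at the same time gave 0.0709 for genes that rose at 6 h, and a ratio of means gave 0.296 at 6 h and 0.309 at 18 h.

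The doses shared many called genes. At 6 h, 289 genes were up and 64 down at both doses, against 106 in all for independent lists, and 31 were called in opposite directions. At 18 h, 552 were up and 371 down at both, against 254 for independent lists, with 65 opposite. Both doses were compared with the same 2 vehicle libraries, so part of this overlap may come from the shared controls. Each dose then had its own single vehicle library, in both pairings (chosen after seeing the data). Correlations were 0.450 or 0.343 at 6 h and 0.561 or 0.476 at 18 h. These libraries differed in replicate number, which entered the doses' folds with opposite signs, so this cannot show what shared controls add. Groups simulated as unchanged against the same vehicle libraries shared at most 1 called gene over 20 simulations. No gene was made to change there, so that count cannot show what shared controls add to lists of called genes. The simulated fold changes had a correlation of 0.499 at 6 h and 0.503 at 18 h and a covariance of 0.0257 and 0.0260. The data gave correlations of 0.509 and 0.610 and covariances of 0.165 and 0.253. The values from the data cover the 11020 genes with an average log2 CPM of at least 2 (a floor chosen after the data were seen). Between the times, 388 genes were called in the same direction at 100 pM, against 29.5 for independent lists and 0 in opposite directions, and 3084 at 10 nM, against 1002 with 118 opposite.

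Of the 71 list calls made by camera over the 9 comparisons, the call of progestin and glucocorticoid response genes at 100 pM for 6 h was the one that held with an estimated correlation, and it was lost (adjusted p = 0.191) where that fit also held the block. Median, mean and test differed in sign for 48 of the 315 pairs of list and comparison, none of them among the calls, and no called list's median changed sign with RLE factors.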

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

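The tests of explanations below were written before their results were seen, except that of scaling on genes chosen at 6 h. A first pattern was that genes changed at 100 pM moved back at 10 nM (181 at 6 h and 409 at 18 h). If noise in the 100 pM libraries, which enter both steps, had made it, at most 50% of the 6 h genes would have both signs again in the 18 h libraries, and 83.4% (151 of 181, exact 95% interval 77.2 to 88.5) had them, but the interval reaches under the 80% set in advance as counting against noise, and of the 18 h genes 69.7% (285 of 409) had both signs at 6 h, above 50% and under 80%. The 18 h median of the smaller step was 6.19 times the largest change in scaling (95% resampling interval 5.84 to 6.62), a shift of the median of all genes by 0.106 (log2, 10 nM against 100 pM at 6 h) with totals free of mitochondrially encoded genes, but choosing genes by both calls fixes this. In the 18 h libraries the 6 h genes that rose and those that fell at 100 pM differed in the direction of their 6 h calls by at least 1.39 (log2) in both steps (95% resampling interval over genes 1.19 to 1.58), where a factor for each library moves both alike, which counts against scaling as the whole cause. A response to 10 nM that is lost or smaller (97 and 285 genes not called against vehicle, 53 and 59 on the same side) or opposite (31 and 65) stays open as an untested hypothesis (630 and 1702 genes in all with the replicate block), as do reads shared between gene copies.

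A second pattern was that replicate 3 differed from replicate 1 in all groups, with 6534 genes called for replicate number in the blocked edgeR fit. After thinning all libraries to the lowest total 98.7% as many were called (98.8 to 100.2 leaving out each group), which counts against depth, though thinning removes a small part of most libraries. Removing each library's trend with GC content left 104% (102.5 to 105.7) and with transcript length 102% (100.9 to 102.3), with 13146 of 13872 genes matched to the reference and the others uncorrected, which counts against those trends as the whole cause. In all 6 groups NF-kB and heat shock genes had a higher mean log2 CPM in replicate 1, and DNA replication and mitosis genes in replicate 3 (chosen after seeing the data). Culture, day and library batch stay open, as the labels give none, and no biological explanation was tested.

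Effects that differed between 18 h and 6 h by a test of the difference itself (interaction term) are given as log2 values, 18 h effect minus 6 h effect. For 100 pM edgeR called 2 genes, MAML2 (-1.22) and NPNT (-1.01), and 0 without any 1 of the 8 libraries. Lists called by camera for 100 pM had medians of 1.10 (DNA replication and S phase), 0.93 (mitosis), 0.42 (G1 regulators), 0.30 (hypoxia response), 0.25 (fatty acid synthesis), 0.20 (glycolysis), 0.13 (unfolded protein response), -0.10 (oxidative phosphorylation), -0.20 (estrogen response) and -0.30 (cytosolic ribosomal proteins), with adjusted p of 0.417 to 0.742 with an estimated correlation. For 10 nM edgeR called 1462 genes (467 to 860 without 1 library), among them with a higher 18 h effect FAM83A (5.12), SLPI (3.04), CLDN8 (2.92), CSRNP3 (2.70), RNF43 (2.62), STARD4 (1.78), ACACB (1.74), ELOVL6 (1.39), PMVK (1.25), ESR1 (1.01), ACSL3 (0.99), ASPM (0.98) and ELOVL5 (0.73). Lower were CTNND2 (-3.53), FGF12 (-3.49), ENTPD3 (-3.26), BCAS1 (-3.02), TPM4 (-2.96), PALLD (-1.51), PXN (-1.15), MYBBP1A (-1.13), NOP2 (-1.12), DKC1 (-1.05), LIMA1 (-0.98), CCND1 (-0.91), NOP14 (-0.91) and ACTN4 (-0.74). Lists called for 10 nM had medians of 0.80 (mitosis), 0.77 (cholesterol synthesis), 0.56 (fatty acid synthesis), -0.55 (actin and adhesion) and -0.84 (ribosome biogenesis), with adjusted p of 0.590 to 0.978 with an estimated correlation. ACACB, ASPM, CCND1, CLDN8, CTNND2, ELOVL5, ESR1, SLPI and STARD4 each lost their call without 5 to 8 single libraries of the 8, for all of them vehicle 1 or 10 nM 1 at 6 h and vehicle 1 or 10 nM 3 at 18 h (without the last of which ASPM was 0.63).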

How the results depend on the processing

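The alternatives were chosen before the data were examined, except the floor on level and the leaving out of a replicate number for the dose ratio and the separate vehicle libraries for the overlap, which were added after seeing the data. The cause of each change below was not tested, and leaving out 1 library changes the balance of replicate numbers as well as the number of libraries. Of the alternative values for named genes, 3473 kept their side of the threshold, 303 lost and 27 gained a call, with no call reversed. Of the 71 list calls 70 were lost with an estimated correlation, fry (a test of each list on its own) lost 36 and gained 40, and the block lost 0 and gained 32. The replicate block ended no call of a named gene and gained 17. With the block the counts were 1696 and 4728 (100 pM at 6 h and 18 h), 8662 and 7767 (10 nM at 6 h and 18 h), 8231 and 6958 (10 nM against 100 pM at 6 h and 18 h), 777 and 4863 (100 pM and 10 nM effects between times), 4 (vehicle over time), 686 and 630 (graded and opposed at 6 h) and 1221 and 1702 (at 18 h), and the dose ratio of genes that fell 0.233 at 6 h and 0.467 at 18 h. DESeq2 gave 836 and 2203 (100 pM at 6 h and 18 h), 107 and 2298 (effects between times), 269 and 285 (graded and opposed at 6 h) and 480 and 623 (at 18 h). The 100 pM difference between times had 1 gene with RLE factors, 5 without the low-count filter, 6 with a stricter filter and 0 leave-one-out. The 6 libraries of 1 time alone gave 655 for 100 pM at 18 h, 95 graded at 6 h, and 149 graded and 168 opposed at 18 h. Leave-one-out counts were 221 to 308 (100 pM at 6 h), 512 to 845 (100 pM at 18 h), 4070 to 4579 and 3202 to 3588 (10 nM at 6 h and 18 h), 3281 to 4242 and 2286 to 2900 (10 nM against 100 pM), 467 to 860 (10 nM between times), 58 to 124 and 75 to 135 (graded and opposed at 6 h) and 129 to 269 and 159 to 415 (at 18 h). Dose ratios over genes called at the same time were 0.0709 (up at 6 h), 0.172 (down at 6 h) and 0.344 (down at 18 h), from means 0.296 (up at 6 h), 0.309 (up at 18 h) and 0.383 (down at 18 h), and with RLE factors 0.248 (up) and 0.389 (down) at 18 h. With the floor of log2 CPM they were 0.246 and 0.443 for genes that fell at 6 h and 18 h, and without replicate 1 or 3 they were 0.225 to 0.234 and 0.440 to 0.441. At 34204970 to 41373890 counts a library, depth limits genes at few counts, whose folds are bounds or have wide intervals.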

Other observations

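None of the tests here was chosen after its result was seen. Of the 35 lists tested, 14 were not called by camera when the doses were compared with vehicle or each other at either time, the counts here being those at 10 nM for 18 h with the camera adjusted p. Estrogen response genes had 9 of 33 up and 13 down (0.775), EGFR ligand and ERBB genes 4 of 17 up and 6 down (0.775), immediate-early genes 6 of 29 up and 5 down (0.830), apoptosis regulators 7 of 27 up and 4 down (0.507) and p53 targets 4 of 20 up and 3 down (0.629). Wnt and RANKL genes had 3 of 15 up and 4 down (0.777), mesenchymal genes 3 of 17 up and 7 down (0.119), actin and adhesion genes 6 of 31 up and 11 down (0.163) after 15 of 31 up and 6 down at 6 h (0.108), basal keratins 5 of 18 up and 2 down (0.777), heat shock genes 3 of 13 up and 0 down (0.462), NF-kB genes 1 of 21 up and 0 down (0.777), mitochondrially encoded genes 0 of 13 up and 0 down (0.721) and reference genes 1 of 12 up and 1 down (0.777). The heat shock, NF-kB and reference genes called were DNAJB1, BAG3, CRYAB, SOD2 and HPRT1, up, and ACTB, down. Adjusted over the list alone the counts were the same but for estrogen response (11 up and 13 down), EGFR ligands (6 up and 7 down), apoptosis (8 up and 4 down) and keratins (6 up and 5 down). The block gave 11 up and 9 down for immediate-early, 10 up and 9 down for apoptosis, 11 up and 7 down for p53, 9 up and 17 down for actin, 8 up and 6 down for keratins, 7 up and 2 down for heat shock, 5 up and 4 down for NF-kB and 1 up and 2 down for mitochondrially encoded. The median and the mean had opposite signs for EGFR ligands, apoptosis, Wnt and NF-kB.

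Of markers of other cell types at 10 nM for 18 h, fibroblast genes had 1 of 7 up and 1 down (camera adjusted p = 0.585), THY1 up and COL1A1 down, immune genes 0 of 4 up and 0 down, and endothelial genes 1 of 2 up and 0 down (VWF), with VWF and ESAM up at 6 h. Members named here were chosen after their values were seen.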
